A study of Mus musculus with 6 samples.

How the data were processed

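Mouse brain RNA of the 3 WT and 3 A53T samples was enriched for circRNA, made into libraries with a kit that marks strand and sequenced in paired reads, per the labels' protocols. The deposited table holds, for each circRNA, the count of back-splice junction reads in each library, and next to it the deposited log2 CPM that the authors computed with edgeR, per the file headers. The submitters' processing notes name cutadapt 1.9.3, STAR, edgeR 3.16.5 and the mouse build mm39. The circRNA caller, the annotation and whether counting used the strand are not given in the sources used here. The table also gives each circRNA's class, host gene, transcript and predicted sequence length, called spliced length here. For 284 of the 285 circRNAs with a database identifier this length equals the genomic span. Each listed circRNA had at least 2 reads in some library, so circRNAs with fewer reads in every library are not listed. The deposited log2 CPM was recomputed from the counts with a prior count of 2, with a largest difference of 0.122. It was used for this check only, and a count of 0 stands at about 5.99 in it.

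All tests were made on the deposited counts. Library size was the sum of junction reads of all circRNAs, 25217 to 36390 per library, so 1 read was worth 27.5 to 39.7 CPM before TMM scaling. circRNAs with no gene name (338, holding 0.690 to 0.828% of the reads of a library) stayed in the circRNA test and out of the host gene sums. circRNAs or host genes with at least 5 reads in at least 3 of the 6 libraries were tested. edgeR 4.0.16 (quasi-likelihood, robust, TMM) in R 4.3.3 compared A53T with WT, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate entered. Standard errors were derived from the F statistic. Ratios for groups with 3 reads or fewer were taken over scaled library sizes with exact conditional intervals. Intervals are 95%. That of a fitted log2 fold change carries the spread between samples; Wilson and exact conditional intervals cover counting error only, and PCR reads without molecular identifiers are not independent molecules. Gene lists were tested on host gene sums with camera in limma 3.58.1, with a preset correlation of 0.01 and at least 5 tested members, and with an estimated correlation and fry beside it. Library totals, circRNAs detected at 2 reads, the share of the 10 most abundant circRNAs and shares of classes were compared with two-sided exact permutation tests in scipy 1.17.1. The script was tested on simulated counts, with 200 changed features in each of 10 simulations: unchanged circRNAs were called in 0.227% and unchanged host genes in 0.416% of cases.

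Coordinates are those of the table, in mm39, 1-based. The reference used here was GENCODE M21 on an older build, so no coordinates were converted, and its coordinates served only to find where both builds number positions alike. Exon numbers come from matching each exonic circRNA, by span and predicted spliced length, to runs of exons of its named transcript. Junction sequences come from these reference transcripts. Gene names were those of the table.

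The groups, tests, filters, gene lists, the rule for named genes and the main alternatives were set before the data were examined. The rule named, in each direction, up to 12 circRNAs past the threshold or, where fewer than 3 passed, the 8 with the smallest unadjusted p; the 8 most abundant circRNAs; host genes by the same rule with 6 in each direction; and up to 4 tested genes of each list with the smallest p. Some list genes are not reported here. The alternatives were other scalings (DESeq2 size factors, upper quartile, totals only), other filters, DESeq2 1.42.0, limma-voom, the edgeR exact test, a replicate block and leaving out each replicate. Tests of circRNAs within a host gene, of circRNAs seen in 1 group only, of the start codon share and without the Cdr1os circRNA were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.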

Results

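The series profiled circular RNAs (circRNAs), closed RNA rings recognised in sequencing data by reads that cross a back-splice junction, where the end of a downstream exon is joined to the start of an upstream one. Total RNA from mouse brain was enriched for circRNA and sequenced in 6 libraries, 3 labelled WT (wild type) and 3 labelled A53T. A53T mice are a transgenic model of Parkinson disease named for the mutation they carry. The sample labels give the tissue as brain, whereas the series text speaks of the midbrain substantia nigra; these descriptions differ and were not reconciled here. The labels do not say whether the samples are separate animals, so p-values measure only the spread between these samples, which may be technical. The libraries held 33077, 36390 and 25217 junction reads in WT replicates 1, 2 and 3, and 29839, 32187 and 33313 in A53T replicates 1, 2 and 3. Levels are given in CPM, junction reads scaled to a common library size after TMM.

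The brain circRNAs in the table came mostly from annotated exons of their host genes. The table listed 18136 circRNAs from 5414 named host genes, with 190023 junction reads in all. Exonic circRNAs made up 13133 of them (72.4%), followed by 2716 sense overlapping, 1580 intronic, 372 antisense and 335 intergenic ones. Of the exonic circRNAs, 12794 (97.4%) matched a single run of annotated exons by span and predicted spliced length. They had a median of 4 exons and a median predicted length of 572 nt (interquartile range 362 to 936 nt). Junction reads show only the ends of a circle. Its inner exons and its length, here and below, are therefore predicted and were not observed. Exon 2 was the first exon of 27.7% of the matched circRNAs, exon 1 of 0.40%, and 602 (4.71%) were made of 1 exon. Most circRNAs had few reads: the median was 3 over all 6 libraries, 9197 (50.7%) were read in 1 library only, and the 1596 read in all 6 libraries held 58.4% of the junction reads. Each listed circRNA had at least 2 reads in some library.

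The most abundant circRNA came from Cdr1os, the locus antisense to Cdr1, whose circular transcript is abundant in brain and binds microRNAs. This single-exon circle lay on the plus strand of chromosome X, positions 60226854 to 60229780 in mm39, and corresponded to exon 6 of 7 of a non-coding transcript, 2927 nt long. It took 3.13% of all junction reads. Its back-splice junction, 20 nt on each side, reads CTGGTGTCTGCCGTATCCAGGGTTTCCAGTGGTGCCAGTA in the reference transcript. Its level was 22786 ± 12238 CPM in WT and 40246 ± 1486 CPM in A53T (SD, n = 3 each), a log2 fold change of 0.82 (standard error 0.51, 95% interval -0.54 to 2.18), which did not pass the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.993). WT replicate 1 had 304 reads of it, 0.919% of its junction reads (95% Wilson interval 0.822 to 1.03%), against 3.14% in WT replicate 2 and 2.81% in WT replicate 3. The A53T libraries held 4.02%, 3.86% and 4.06%. limma-voom alone called Cdr1os (log2 fold change 1.05, adjusted p = 0.00158), while over the other settings the adjusted p ran from 0.222 to 1.00; without WT replicate 1 the log2 fold change was 0.45. Whether counting used the strand is not stated, so reads of Cdr1os and of its antisense partner Cdr1 could not be told apart with certainty.

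**Figure D1:**
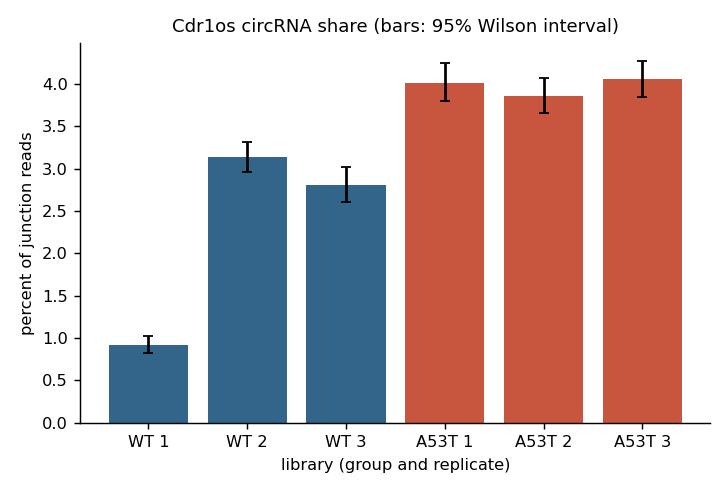
Share of the junction reads of each library (y axis, percent) taken by the Cdr1os circRNA, for the 3 WT and 3 A53T libraries (x axis). Bars start at 0 and error bars are 95% Wilson intervals, which cover counting error only; WT replicate 1 is lowest at 0.919% and the A53T libraries lie between 3.86% and 4.06%.

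The other 7 of the 8 most abundant circRNAs had nearly the same level in both groups. They came from Cdyl, a chromodomain protein gene, Ankrd12, Tulp4, Rims2, an active zone protein gene of the presynaptic terminal, Zfp148, Zfp609 and Ankib1. The Cdyl circRNA, exon 5 of 10 on chromosome 13 (35999892 to 36000558, plus strand), had 10131 ± 1004 CPM in WT and 10058 ± 988 CPM in A53T (SD, n = 3 each). The Ankrd12 circRNA, exons 2 to 8 of 13, had 8203 ± 534 CPM in WT and 8877 ± 1326 CPM in A53T. The Tulp4 circRNA, the intronic one of the 8, had 6831 ± 128 and 7950 ± 1003 CPM. Rims2 exons 20 to 22 gave 5137 ± 1467 and 5277 ± 900.1 CPM. Log2 fold changes were 0.11 for Ankrd12, 0.22 for Tulp4, 0.15 for Ankib1, 0.03 for Rims2, -0.07 for Zfp148, and -0.01 for both Cdyl and Zfp609; those of Ankrd12, Rims2, Zfp148, Cdyl and Zfp609 turned sign when single libraries were left out. Their standard errors lay between 0.15 and 0.19, and none passed the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p of 0.993 or more).

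Totals, diversity and classes of circRNAs were compared between A53T and WT brain first. WT libraries held 31561 ± 5739 junction reads and A53T libraries 31780 ± 1772 (SD, n = 3 each; exact permutation test, two-sided, p = 0.9), and 5342 ± 716 against 5378 ± 252 circRNAs had at least 2 reads (exact permutation p = 1). Both differences turned sign without WT replicate 3 and without A53T replicate 3. The 10 most abundant circRNAs took 7.80 ± 1.19% of the reads in WT and 9.43 ± 0.17% in A53T. With 3 samples against 3 the exact permutation p cannot go below 0.1, which was the value here. Without the Cdr1os circRNA, an alternative chosen after seeing the data, the shares were 6.04 ± 0.17% and 6.03 ± 0.09%. Exonic circRNAs held 86.8 ± 0.11% of the reads in WT and 86.5 ± 0.62% in A53T, intronic ones 3.51 ± 0.34% and 3.71 ± 0.30%, antisense ones 0.614 ± 0.120% and 0.742 ± 0.071%, intergenic ones 0.782 ± 0.032% and 0.729 ± 0.048%, and sense overlapping ones 8.32 ± 0.22% and 8.30 ± 0.49% (SD, n = 3 each). Exact permutation p-values for these 5 classes lay between 0.1 and 0.9, and between 0.5 and 0.9 after Benjamini-Hochberg adjustment over the 5.

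The central question of the design was which circRNAs differ between A53T and WT brain. Among the circRNAs with the smallest unadjusted p, a circRNA of the active zone gene Erc2 had 400.0 ± 22.7 CPM in WT and 31.2 ± 54.0 CPM in A53T (SD, n = 3 each), and one of the pseudogene Nlrp5-ps had 409.8 ± 95.2 and 1171 ± 389 CPM. A circRNA of Npas2, a clock-related transcription factor gene, had 1039 ± 365 CPM in WT and 446.1 ± 35.2 CPM in A53T, and one of Kcnj6, a potassium channel gene of dopaminergic and other neurons, had 590.6 ± 97.2 and 1113 ± 384 CPM. None of these differences passed the test once all circRNAs were accounted for.

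Of 1214 circRNAs tested, from 822 host genes and with 55.3% of the reads, 0 passed an adjusted p of 0.05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 57, of which 28 were higher and 29 lower in A53T, against 60.7 expected by chance. DESeq2 gave 0 adjusted calls and 51 unadjusted, the edgeR exact test 0 and 58, and limma-voom 1 (Cdr1os) and 56. All samples of one group lay above all of the other for 137 of the 1214 circRNAs (11.3%), where chance gives 10%. The biological coefficient of variation was 33.7%. In simulated data with these depths and spreads, the test called 15.2% of 2-fold, 58.7% of 4-fold and 78.5% of 8-fold changes among 1214 circRNAs; for circRNAs with more than 30 reads on average it called 70.8% of 2-fold and 98.2% of 4-fold changes. In each simulation 200 circRNAs were changed at once, and there 2-fold differences were mostly called for abundant circRNAs and mostly not for the others. With fewer changed circRNAs the Benjamini-Hochberg adjustment is stricter, and that case was not simulated. These rates may therefore be too high for the real data.

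**Figure D2:**
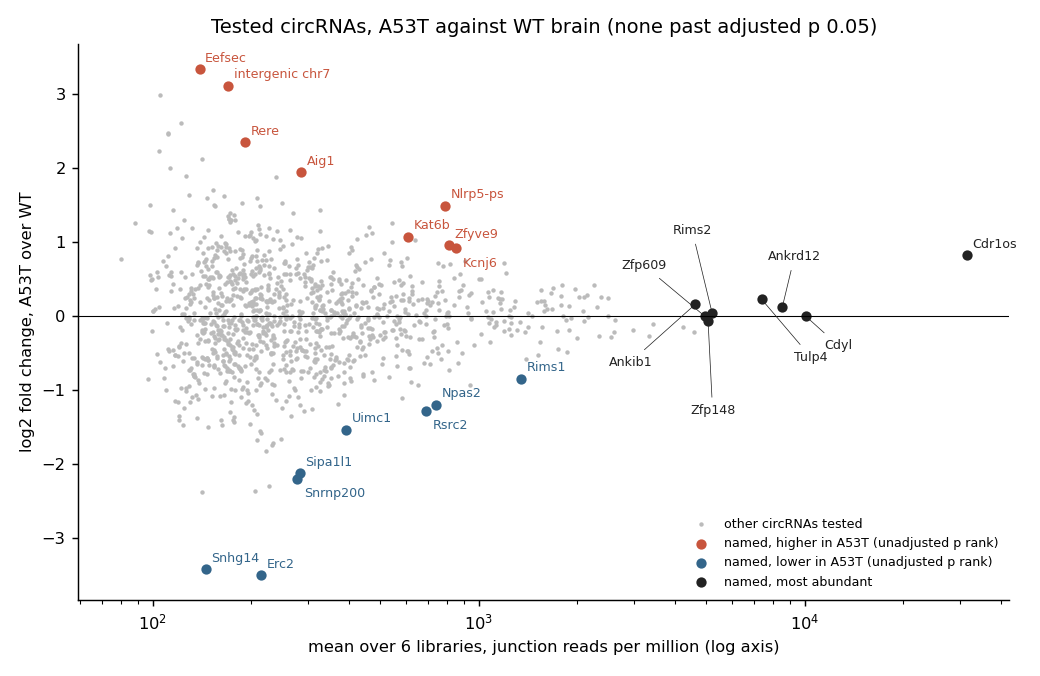
Log2 fold change of A53T over WT (y axis) against mean level over the 6 libraries in CPM (x axis, log scale) for the 1214 tested circRNAs. Grey points are other circRNAs, red and blue points the 8 higher and 8 lower ones with the smallest unadjusted p, and black points the 8 most abundant; 0 passed an adjusted p of 0.05.

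The 8 circRNAs higher in A53T with the smallest unadjusted p, none past the threshold, came from Nlrp5-ps, an unnamed intergenic locus, Eefsec, Zfyve9, Rere, Aig1, Kcnj6 and Kat6b. The Nlrp5-ps circRNA spanned exons 2 to 11 of 13 of a non-coding transcript on chromosome 7 (14312661 to 14343264, minus strand, mm39). Its reads numbered 17, 15 and 8 in the WT libraries and 38, 48 and 24 in the A53T libraries, a log2 fold change of 1.49 (standard error 0.35; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.216). Its junction reads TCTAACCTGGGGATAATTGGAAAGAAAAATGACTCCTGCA in the reference transcript; as a pseudogene it may share reads with its parent gene, so its counts are uncertain. It passed with a filter of at least 10 reads (adjusted p = 0.0367) and without A53T replicate 3 (adjusted p = 0.00963), and its adjusted p ran from 0.00963 to 0.583 over all settings. The Kcnj6 circRNA was exon 3 of 5, wholly coding, on chromosome 16 (94633158 to 94634078, minus strand), with a log2 fold change of 0.91 (standard error 0.33, adjusted p = 0.657 by the same test). Its junction reads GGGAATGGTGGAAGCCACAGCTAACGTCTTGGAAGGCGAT.

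Higher in A53T, but with few reads, were circRNAs of Eefsec, which encodes the elongation factor for selenocysteine, and of the intergenic locus on chromosome 7 (60662780 to 60667780, minus strand). Eefsec exons 2 to 4 had 2 reads over the WT libraries and 24 over the A53T libraries, a ratio of 12.2 with a 95% counting interval of 3.02 to 106. Both WT reads lay in WT replicate 3. Without it the fitted log2 fold change went from 3.33 to 6.08, which depends on the prior count. Taking 3 reads as a floor for the WT group gave a ratio of 5.91, which carries no interval for counting error. The intergenic circRNA had 3 and 29 reads, a ratio of 9.80 (interval 3.04 to 50.3); without WT replicate 3 it had 1 and 29, a ratio of 21.4 (interval 3.55 to 876). Zfyve9 exons 2 to 4, which hold the start codon, had 553.9 ± 89.6 CPM in WT and 1065 ± 226 CPM in A53T. Rere exon 2 had 57.4 ± 49.8 and 326.8 ± 102.3 CPM, Aig1 117.1 ± 103.6 and 454.9 ± 246.5 CPM, and Kat6b, a histone acetyltransferase gene, 395.8 ± 149.1 and 822.5 ± 191.4 CPM (SD, n = 3 each). The log2 fold change of Aig1 was 1.94, against 1.35 without WT replicate 1 and 2.66 without WT replicate 2. Adjusted p-values of these 6 circRNAs lay between 0.469 and 0.657 (edgeR quasi-likelihood, Benjamini-Hochberg).

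The 8 circRNAs lower in A53T with the smallest unadjusted p, none past the threshold, came from Erc2, Npas2, Snhg14, Snrnp200, Rsrc2, Sipa1l1, Rims1 and Uimc1. The Erc2 circRNA joined exons 12 and 13 of 16, all coding sequence, on chromosome 14 (27802089 to 27863338, plus strand, mm39). It had 13, 14 and 11 reads in the WT libraries and 0, 3 and 0 in the A53T libraries, a ratio of WT to A53T of 12.5 with a 95% counting interval of 3.96 to 63.3. Its fitted log2 fold change was -3.50 (standard error 0.90; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.266). Without A53T replicate 2, which held all 3 A53T reads, the fitted value was -6.66, which depends on the prior count. Taking 3 reads as a floor for the A53T group gave a ratio of WT to A53T of 8.25, which carries no interval for counting error. Without that replicate the adjusted p in the same test was 0.0400. It ran from 0.0400 to 0.903 over the settings that kept this circRNA, which fell under the filter whenever a WT replicate was left out. Its junction reads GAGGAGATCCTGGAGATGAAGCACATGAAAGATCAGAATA. The other 2 tested circRNAs of Erc2 had log2 fold changes of 0.21 and 0.25.

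Npas2 exons 2 to 5, on chromosome 1 (39302400 to 39339814, plus strand), hold the start codon and had a log2 fold change of -1.20 (standard error 0.36). The Snhg14 circRNA lay on chromosome 7 (59093520 to 59101126, minus strand) within a long non-coding transcript of the imprinted Prader-Willi and Angelman region, which is rich in repeated units, so its assignment is uncertain. It had 25 reads over the WT libraries and 2 over the A53T libraries, a ratio of 12.3 (95% counting interval 3.08 to 107). Snrnp200, a spliceosome helicase gene, had 458.5 ± 219.3 CPM in WT and 95.4 ± 61.8 CPM in A53T for exons 39 to 43 (SD, n = 3 each). Rsrc2 exons 2 to 3 had 981.8 ± 172.5 and 395.9 ± 260.4 CPM, Sipa1l1 exon 2 had 462.6 ± 268.3 and 104.0 ± 98.2 CPM, and Uimc1 exons 7 to 10 had 585.1 ± 275.3 and 201.5 ± 14.5 CPM. A sense overlapping circRNA of Rims1, an active zone gene, had 1743 ± 396 CPM in WT and 963.2 ± 275.8 CPM in A53T. Adjusted p-values of these 7 lay between 0.469 and 0.502 (edgeR quasi-likelihood, Benjamini-Hochberg).

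**Figure D3:**
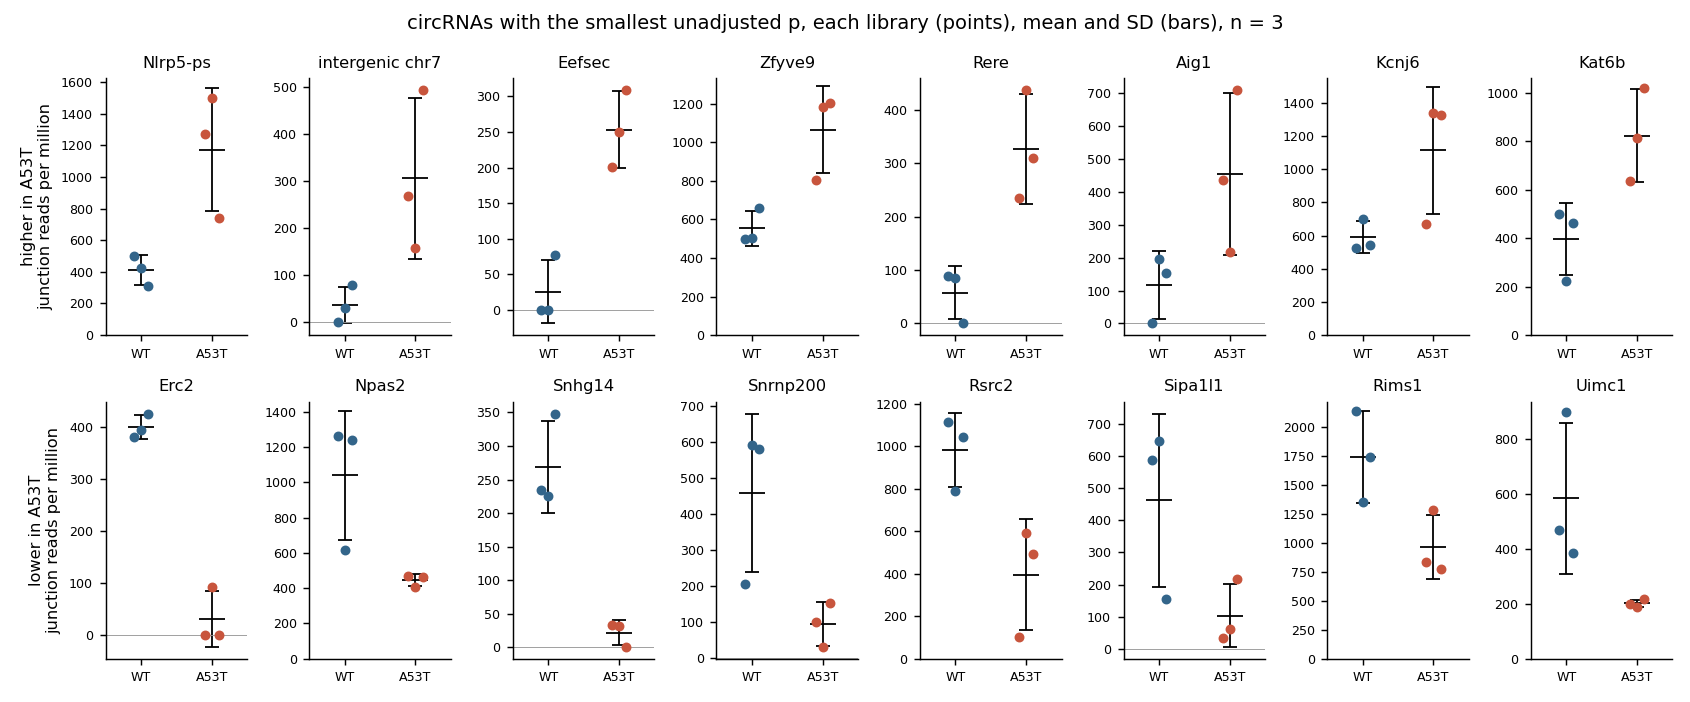
Level of 16 circRNAs in each library (points, CPM, y axis from 0 or just below) by group (x axis), with mean and SD (n = 3). The upper panels show the 8 higher and the lower panels the 8 lower in A53T with the smallest unadjusted p; the Erc2 circRNA has 0 reads in 2 of the A53T libraries.

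Junction reads were also summed over all circRNAs of a host gene, which raises the depth. For some hosts the sum is mostly the reads of a circRNA named above. Kcnj6 had 28.8 reads per library on average, against 27.2 for its circRNA. The values were 30.3 and 25 for Nlrp5-ps, 10.3 and 8.67 for Snrnp200, and 35 and 23.2 for Npas2. Their host results are therefore not separate from those above. Sums can also hide circRNAs of a host that move apart. Higher in A53T at the smallest unadjusted p were Nlrp5-ps, Minar1, Syne1, which encodes a nuclear envelope protein, Tcf20, the non-coding gene A230006K03Rik, and Kcnj6. Lower were Phactr1, which encodes a regulator of phosphatase and actin, Npas2, Snrnp200, Plekha5, Shank3, a scaffold gene of the postsynaptic density, and Ralgps1. Phactr1 had 553.3 ± 141.4 CPM in WT and 95.96 ± 111.9 CPM in A53T (SD, n = 3 each), a log2 fold change of -2.47 (standard error 0.68). Without A53T replicate 2 it was -3.94, with 51 WT and 2 A53T reads, a ratio of WT to A53T of 16.6 (95% counting interval 4.37 to 141). Tcf20 had 1217 ± 229 and 2126 ± 231 CPM, and Shank3 785.9 ± 251.2 and 346.6 ± 122.8 CPM. None of them passed the test.

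Of 1377 host genes tested, 0 passed an adjusted p of 0.05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.249 (Nlrp5-ps). At an unadjusted p under 0.05 there were 66, of which 36 were higher and 30 lower, against 68.9 expected by chance. DESeq2 gave 0 adjusted calls and 48 unadjusted, the edgeR exact test 0 and 60, and limma-voom 1 (Cdr1os, adjusted p = 1.9e-05) and 65. Groups did not overlap for 144 host genes (10.5%), where chance gives 10%. Log2 fold changes of the other named host genes were 1.35 for Nlrp5-ps, 1.38 for Minar1, 1.58 for Syne1, 0.79 for Tcf20, 1.06 for A230006K03Rik, 0.96 for Kcnj6, -1.03 for Npas2, -2.02 for Snrnp200, -0.66 for Plekha5, -1.20 for Shank3 and -0.65 for Ralgps1. In simulated data with 200 host genes changed at once, the test called 22.5% of 2-fold and 63.7% of 4-fold changes among 1377 host genes.

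Gene groups that fit the tissue and the model were compared as 24 lists with 819 distinct genes, of which 243 were tested. In all lists, higher and lower refer to junction reads summed over the circRNAs of a gene. Linear mRNA was not measured here, so the values give neither the expression of a gene nor the share of a cell type. The dopaminergic neuron list stood highest: of 30 genes, 11 had a circRNA and 5 were tested, 4 of them higher in A53T, with a median log2 fold change of 0.56. Kcnj6 was at 0.96, Dcc, an axon guidance receptor gene, at 0.62, Satb1 at 0.56 and Erbb4 at 0.52. In the autophagy and lysosome list 7 of 8 tested genes were higher, including Vps41 at 0.60, Vmp1 at 0.50, Atg4c at 0.44 and Tax1bp1 at 0.43. In the pan-neuronal list 6 of 8 were lower, including the synaptic vesicle genes Syn1 at -0.94 and Syt1 at -0.77 and the ankyrin gene Ank3 at -0.57. The 2 higher ones were Ank2, another ankyrin gene, at 0.42 and Rbfox1 at 0.29. Leaving out 1 library moved 4 of these genes by over 1.5 times: Erbb4 was at 1.52 without WT replicate 2, -0.02 without WT replicate 3 and -0.22 without A53T replicate 3, Vps41 at 1.39 without WT replicate 1, Syt1 at -1.44 without A53T replicate 2 and Ank3 at -1.30 without A53T replicate 3. None of these lists passed the test.

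Over the 17 lists with at least 5 tested genes, 0 passed an adjusted p of 0.05 in camera with a preset correlation of 0.01. The dopaminergic neuron list was the 1 list with an unadjusted p under 0.05 (p = 0.0233, adjusted p = 0.396); with an estimated correlation p = 0.0815 and fry gave p = 0.0789. fry, which asks whether the genes of a list move on balance one way, gave its smallest p for the oligodendrocyte list (p = 0.0158, adjusted p = 0.268), and 0 lists passed after adjustment by either. Over all genes tested 0 list members passed (edgeR quasi-likelihood, Benjamini-Hochberg), and 11 of the 243 had an unadjusted p under 0.05. Adjusted over the list alone, 1 gene of the dopaminergic neuron list passed, Kcnj6 (adjusted p = 0.0322), and 1 of the striatum list, Phactr1 (adjusted p = 0.00250). In all other lists the count adjusted over the list alone was 0. Kcnj6 did not pass in the ion channel list of 22 tested genes (adjusted p = 0.0831). Such an adjustment covers only the 5 or 4 tested genes of a list and not the search over 24 lists. Over all host genes the adjusted p was 0.703 for Kcnj6 and 0.425 for Phactr1. In simulated data a 1.5-fold shift of all members passed in 25% of 20 simulations for the 5 dopaminergic genes and in 100% for the 25 presynaptic genes. There each gene was drawn independently and all members moved one way. Correlated members or members that go both ways were not simulated, so these rates may be too high for the real data.

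**Figure D4:**
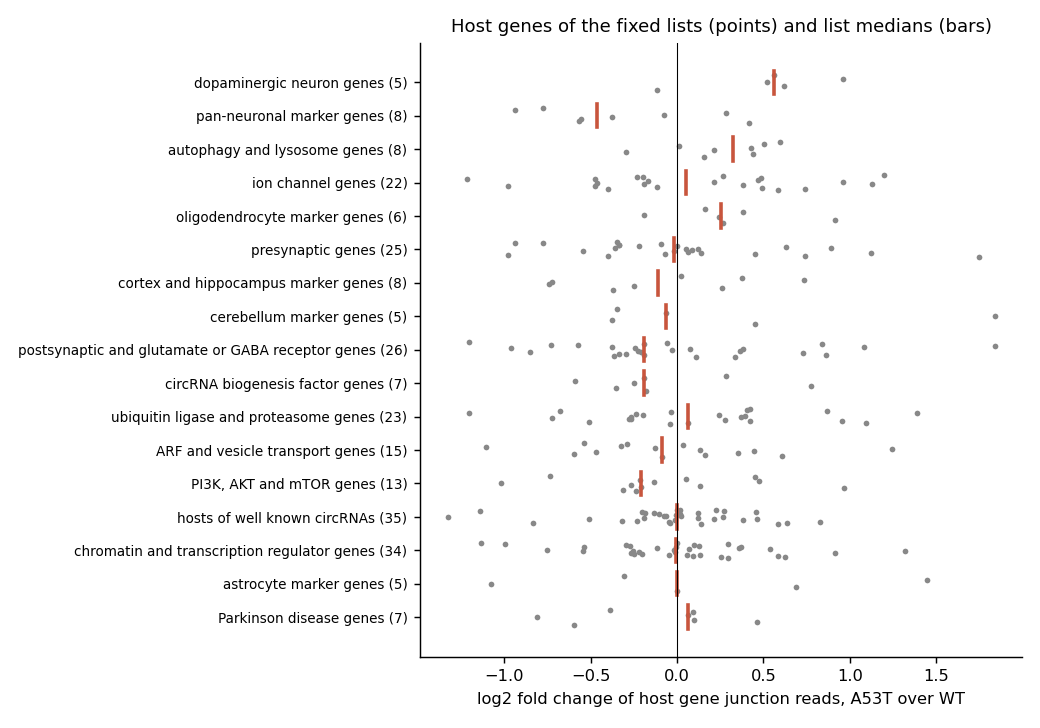
Log2 fold change of host gene junction reads, A53T over WT (x axis), of each tested gene (points) in the 17 lists with at least 5 tested genes (y axis, number tested in brackets, ordered by camera p), with list medians as bars. The medians run from -0.47 for the pan-neuronal list to 0.56 for the dopaminergic neuron list; 0 lists passed an adjusted p of 0.05.

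Among the lists tied to the study's themes, the Parkinson disease list had 4 of 7 tested genes higher and 3 lower, with Gigyf2 at 0.46, Dnajc6 at -0.60, Lrrk2 at -0.81 and Vps13c at -0.39. Its median was 0.06, its mean -0.15, camera gave it a downward and fry an upward direction. The list of PI3K, AKT and mTOR genes had 5 higher and 8 lower (median -0.21), with Igf1r at 0.97, Pdpk1 at -1.02, Pik3c2a at 0.48 and Rps6kb1 at -0.73. The list of ARF and vesicle transport genes had 7 higher and 8 lower (median -0.09), with Sec24a at -1.10, Agap1 at 0.61, Copg2 at 1.25 and Arfgef2 at -0.47. Vps13c was at -1.10 without A53T replicate 3 and at 0.14 without WT replicate 2; without WT replicate 2 Igf1r was at 1.98 and Copg2 at 2.32, the latter with 3 WT and 25 A53T reads, a ratio of 5.196 (95% counting interval 1.59 to 26.9). Leaving out single libraries turned the sign of these medians, which ran from -0.26 to 0.13 for the Parkinson disease list, from -0.26 to 0.015 for PI3K, AKT and mTOR and from -0.26 to 0.087 for ARF and vesicle transport. Camera p-values of these lists were 0.945, 0.741 and 0.708, and 0.199 for the autophagy and lysosome list (median 0.32).

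Synaptic and channel genes went both ways. Of 25 presynaptic genes 11 were higher and 14 lower (median -0.02, mean 0.03, camera direction down), with Cacna2d1 at -0.98, Dmxl2 at 1.12 and Rims1 at -0.22. Of 26 postsynaptic and receptor genes 10 were higher and 16 lower (median -0.19), with Shank3 at -1.20, Grm4 at 1.84, Grin3a at 1.08 and Grm5 at -0.73. A53T replicate 2 held 22 of the 32 A53T reads of Grm4, which was at 0.76 without it; without WT replicate 2 Grm4 was at 3.158, with 2 WT reads, a ratio of 9.98 (95% counting interval 2.55 to 85.9). Grm5 was at -1.49 without A53T replicate 3. Of 22 ion channel genes 11 were higher and 11 lower (median 0.05), with Trpm3 at 1.20 and Cacna1a at 0.74. The ubiquitin ligase and proteasome list had 12 higher and 11 lower (median 0.07; Ubr1 at 1.39, Usp25 at 0.87, Ubr2 at -1.21, Herc1 at 0.95). The chromatin list had 17 and 17 (median -0.00411, mean 0.01, camera direction down; Crebbp at 0.92, Hdac9 at -0.75, Nsd2 at -0.29, Kmt2a at 0.54). The list of circRNA biogenesis factors had 2 and 5 (median -0.19; Elavl2 at 0.77, Celf2 at -0.36, Nova2 at -0.59, Rbfox1 at 0.29). The hosts of well known circRNAs had 17 and 18 (median -0.00301, mean -0.02, camera direction up; Camsap1 at -0.83, Tulp4 at 0.27, Fat3 at 0.38). Leaving out 1 library put Ubr1 at 0.79 (WT replicate 1), Usp25 at 1.53 (WT replicate 3), Nova2 at -1.24 (A53T replicate 3) and Camsap1 at -1.44 (A53T replicate 2). The medians of the ion channel, ubiquitin, chromatin, circRNA biogenesis and well known host lists turned sign when single libraries were left out.

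Junction reads from marker genes of other cell types and of brain regions were compared beside these lists. Oligodendrocyte genes were higher for 5 of 6 (median 0.25; Dock10 at 0.92, Slc44a1 at 0.38, Pex5l at 0.24, Qk at -0.19). Astrocyte genes were higher for 2 of 5 (median -0.00276, mean 0.15, camera direction up; Slc1a2 at 1.45, Prex2 at -1.08, Npas3 at 0.69, Slc4a4 at -0.31). Cortex and hippocampus genes were higher for 4 of 8 (median -0.11; Nell2 at -0.72, Mef2c at -0.74, Ptprd at 0.38, Arpp21 at -0.37), and cerebellum genes for 2 of 5 (median -0.06, mean 0.30, camera direction up; Grm4 at 1.84, Unc13c at -0.35, Cadps2 at 0.45). Lists with fewer than 5 tested genes were not tested as lists. They were the striatum list (4 tested; Phactr1 at -2.47, Ano3 at 0.58, Foxp1 at -0.26), the thalamus and midbrain list (4; Sox5 at -0.56, Ntng1 at 0.79, Rora at 0.16), the oligodendrocyte precursor list (4; Tnr at 1.74, Dscam at -0.32, Pcdh15 at -0.12, Ptprz1 at 0.13), the mitochondrial list (4; Atp5c1 at -0.90, Ogdh at 0.39, Ndufs1 at -0.50, Rhot1 at 0.20), the microglia list (2; Plxdc2 at -0.80, Elmo1 at 0.86), the immediate early list (1; Homer1 at -0.19) and the vascular list (0). Single libraries moved several of these genes by over 1.5 times or turned their sign. Without WT replicate 1 Pex5l was at 0.98, Cadps2 at 1.53, Ntng1 at 2.21 and Ndufs1 at 0.06. Without WT replicate 2 Slc44a1 was at 1.14, Slc1a2 at 0.83, Ntng1 at 0.16, Ndufs1 at -1.13, Homer1 at 0.14, Rhot1 at -0.29, Foxp1 at 0.11, Grm4 at 3.158 and Tnr at 3.57, the last with 1 WT and 23 A53T reads, a ratio of 14.3 (95% counting interval 2.33 to 591). Without WT replicate 3 Npas3 was at 1.59, Pex5l at -0.13, Qk at 0.22, Cadps2 at -0.00051 and Rora at -0.07. Without A53T replicate 1 Npas3 was at 0.01, Cadps2 at -0.15 and Rora at -0.03. Without A53T replicate 2 Phactr1 was at -3.94, Grm4 at 0.76 and Pcdh15 at 0.14, and without A53T replicate 3 Plxdc2 was at -1.76 and Rora at -0.14. limma-voom put Ndufs1 at 0.95, Rhot1 at -0.43, Ptprz1 at -0.17, Rora at -0.0060, Slc1a2 at 2.20 and Ntng1 at 1.92, and the replicate block put Rhot1 at -0.18 and Ptprz1 at -0.03.

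The circRNA that the series title names could not be matched. An identifier from a circRNA database was given for 285 of the 18136 circRNAs, and 0 of these identifiers end in its number. The named circRNA was not identified here, so whether it is among the listed or tested ones is unknown.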

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

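Tests of the start codon share and without the Cdr1os circRNA were added after the data had been seen; the other settings given here were planned. The labels number the replicates 1 to 3 in both groups and do not say whether equal numbers mark paired samples. Deviations of same-numbered libraries correlated at -0.03, 0.01 and 0.02 and none exceeded 0.1. No pairing showed, but counting error at few reads per circRNA could hide it. With the replicate block the circRNA test gave 0 adjusted and 47 unadjusted calls and the host gene test 0 and 63, so the pairing term changed no call; under the block Zfp609 was at 0.010, Rhot1 at -0.18, Ptprz1 at -0.032 and the median of well known hosts at 0.014. Adjusted calls of circRNAs numbered 0 in both directions under every scaling, DESeq2 and the edgeR exact test. They were 1 higher with limma-voom (Cdr1os) and 1 higher with at least 10 reads (Nlrp5-ps), where fewer circRNAs (519) were tested. Unadjusted p under 0.05 with at least 2-fold gave 21 higher and 22 lower circRNAs, and 24 higher and 16 lower host genes; limma-voom called 1 higher host gene (Cdr1os). Against 57 unadjusted circRNAs of 1214, there were 214 of 18136 with no filter (906.8 expected by chance). With at least 2 reads there were 135 of 3420 (171) and with at least 10 reads 34 of 519 (25.95). The filter of edgeR itself gave 35 of 492 (24.6). Against 66 host genes, the same filters gave 130 of 5414 (270.7), 105 of 2595 (129.75), 46 of 767 (38.35) and 47 of 742 (37.1). Counts lay below the expected ones with the loose filters and above them with the strict ones. The expected counts take p as uniform. Features with very few reads can hardly reach 0.05, so these counts may be too high for the loose filters, where no null was simulated. Leaving out each replicate gave 0 to 1 adjusted circRNAs higher (Nlrp5-ps without A53T replicate 3) and 0 to 1 lower (Erc2 without A53T replicate 2), and 0 host genes and 0 lists each time; the cause was not tested. Some values changed sign. For Cdyl the log2 fold change was 0.0019 with upper quartile scaling, 0.033 with no filter, 4.6e-05 with DESeq2 and 0.0058 with limma-voom; for Zfp609 it was 0.00035, 0.034, 0.00047 and 0.044 under the same settings and 0.00019 with at least 2 reads. limma-voom put Ndufs1 at 0.95, Rhot1 at -0.43, Ptprz1 at -0.17 and Rora at -0.0060. On single circRNAs the ion channel median was -0.19 and the PI3K, AKT and mTOR median 0.11. Leave-one-out ranges that crossed 0 were -0.081 to 0.060 for Cdyl, -0.0051 to 0.20 for Ankrd12, -0.18 to 0.23 for Rims2, -0.14 to 0.052 for Zfp148, -0.10 to 0.20 for Zfp609, -1.10 to 0.14 for Vps13c, -0.15 to 1.53 for Cadps2, -0.22 to 1.52 for Erbb4, -0.46 to 0.14 for Homer1, -1.13 to 0.058 for Ndufs1, -0.29 to 0.68 for Rhot1, -0.50 to 0.22 for Qk, -0.13 to 0.98 for Pex5l, -0.50 to 0.14 for Pcdh15, -0.062 to 0.66 for Ank2, -0.58 to 0.11 for Foxp1 and -0.14 to 0.47 for Rora. List medians ranged from -0.26 to 0.087 (ARF and vesicle transport), -0.086 to 0.082 (chromatin), -0.43 to 0.097 (circRNA biogenesis), -0.092 to 0.054 (well known hosts), -0.069 to 0.17 (ion channels), -0.26 to 0.13 (Parkinson disease), -0.26 to 0.015 (PI3K, AKT and mTOR) and -0.11 to 0.14 (ubiquitin). A53T minus WT ranged from -2954 to 2633 for total reads and from -367.7 to 313.8 for circRNAs detected, which was -26.67 at 5 reads and -39.33 after thinning every library to 25217 reads. It ranged from 0.945 to 2.00 percentage points for the 10 most abundant circRNAs, which was -0.014 without Cdr1os; from -0.60 to 0.015 for exonic reads, -0.31 to 0.14 for sense overlapping reads (0.141 without the 10 most abundant circRNAs), 0.067 to 0.19 for antisense, 0.027 to 0.37 for intronic and -0.068 to -0.025 for intergenic reads (0.020 as a share of detected circRNAs). Of 376 values of named circRNAs under other settings 22 changed sign, as did 22 of 1406 of named host genes. Leaving out 1 library moved the fold change by over 1.5 times for 4 of 24 named circRNAs and 23 of 88 named host genes. Low depth limits the circRNA test: with 200 circRNAs changed at once, 4.47% of simulated 2-fold changes were called for circRNAs under 10 reads.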

Other observations

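The tests of circRNA identifiers, of Cdr1os depth and length, of the splits for circRNA calls and without the Cdr1os circRNA were chosen only after the results were seen; those within host genes, of circRNAs in 1 group only and of the start codon share were added after the table had been seen but before their own results were. Host genes differed widely in how many circRNAs they gave. Malat1, a nuclear long non-coding RNA gene, had 65 listed circRNAs with 262 reads in all, whereas Rims2 had 48 with 1891 reads. Dgki and Lrp1b had 42 each, Ptk2 33, and Nbea and Ptprd 31 each. The synaptic genes Rims1 and Anks1b had 26 and 28 circRNAs with 1729 and 988 reads. In all, 363 host genes had 10 or more. Reads on the Y chromosome were found in all 6 libraries (26, 23 and 6 in WT, 13, 8 and 10 in A53T).

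Read in all 3 libraries of one group and in none of the other were 215 circRNAs. They numbered 86 in WT, where WT replicate 3 was the shallowest library (25217 junction reads), which can lower this count. In A53T they numbered 129, and the median was 6 reads in each group. Among those with the most reads, chosen after their values were seen, circRNAs of Ide (1, 15 and 3 reads) and of Tbc1d5 (5, 7 and 2) were read in WT, and circRNAs of 9930021J03Rik (5, 10 and 2), of Lrrc7 (5, 4 and 5) and of Snhg14 (6, 6 and 3) in A53T. Another Tbc1d5 circRNA, with fewer reads, was read in A53T (3, 2 and 4) and not in WT. The Snhg14 circRNA lay at 59335779 to 59371369 on chromosome 7, apart from the Snhg14 circRNA that was lower in A53T. The highest count in the other splits of the 6 samples into 3 and 3 was 204, and 1 of the 10 splits, the real one, reached 215. With 10 splits a share under 0.05 cannot be reached.

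The same holds for the other comparisons. The real split gave 57 circRNAs at an unadjusted p under 0.05 and the highest other split 70, with 3 of the 10 splits at 57 or more. For host genes the values were 66 and 70, with 2 of 10 splits at 66 or more. For gene lists they were 1 and 1, with 5 of 10 splits at 1. One other split, which put WT replicates 1 and 3 with A53T replicate 3, gave 1 adjusted circRNA call.

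The Cdr1os circRNA was low in WT replicate 1, and this library set the spread of the WT group. A shallower library does not account for it: WT replicate 1 had 33077 junction reads, more than the 25217 of WT replicate 3. The other WT libraries had at least 3.07 times the Cdr1os level of WT replicate 1 in CPM, which restates the low share. A loss of long circRNAs would pull down others of at least 1500 nt. Their median log2 ratio in this library to the other WT libraries was -0.19 (standard error 0.09, 130 circRNAs), below 0 but by much less than Cdr1os. This argues against an equal loss of all circRNAs of at least 1500 nt as the whole cause, and a small part stays open. Lengths in this set are predicted, and Cdr1os has 2927 nt. A loss that grows with length could be weak in the set, so that case stays open too. Presynaptic and pan-neuronal hosts had a median log2 ratio of -0.056 (standard error 0.15, 31 genes). As levels are relative to all circRNA reads of a library, fewer neurons could lower these hosts and the total alike. The ratio therefore cannot decide whether this sample held fewer neurons. Differences in neuron content, in the dissected region, among animals or in enrichment may remain, and the labels give nothing to test them.

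No database identifier was given for 17851 circRNAs (98.4%), the 8 most abundant among them. Identifiers were found only in the first parts of chromosomes 4, 6, 9 and 18 and on Y, where coordinates of the table equal those of the older build GRCm38: 100% of the 285 identified circRNAs lay there. Inside these regions 56.4% of 505 circRNAs had one, outside 0 of 17631, a ratio of 3317 when 0 is taken as 3 circRNAs. A candidate explanation is that database coordinates of an older build were compared with mm39 coordinates. The share inside argues against the view that most of these circRNAs are missing from the databases. If so, the absence of an identifier says little about a circRNA of this table, including the one that the series title names.

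A hypothesis that A53T changes which back-splice sites of a host gene are used was tested on 228 host genes with at least 2 tested circRNAs. In edgeR's test of circRNAs against the rest of their host gene 0 passed after Benjamini-Hochberg adjustment and 8 had an unadjusted p under 0.05, led by Erc2 (adjusted p = 0.389). A count of 0 had been set, before this test was run, as speaking against the hypothesis. That was too strict: with 1 circRNA changed in each of 40 of the 228 host genes, over 10 simulations, this test called 0% of these genes at 2-fold, 16% at 4-fold and 43.25% at 8-fold, so the question stays open. A second hypothesis was that circRNAs holding the start codon of their host gene, which could be translated, differ in share. They held 19.7 ± 0.47% of matched exonic reads in WT and 20.9 ± 0.31% in A53T (SD, n = 3 each), with all A53T libraries above all WT libraries. The exact permutation p was 0.1, the smallest that 3 against 3 can give. Without the Cdr1os circRNA the shares were 20.3 ± 0.32% and 21.99 ± 0.34%.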
